A study of Homo sapiens with 14 samples.

How the data were processed

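Messenger RNA was sequenced from WA01 (H1) human embryonic stem cells and from neural crest cultures induced from them for 5 days, in 7 groups of 2 libraries. Per the labels' protocols, cells were grown on Matrigel in DMEM/F12 with B27 and BSA, RNA was isolated with the RNAqueous-micro kit, polyadenylated RNA was selected, and libraries were made with the NEBNext Ultra II directional kit, which keeps the strand. The dose of TGF-beta 1 is printed in the unit the labels give.

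The authors deposited 1 table of raw counts per gene for all 14 libraries. Per the submitters' processing notes, bcl2fastq (version not given in the sources used here), HISAT2 2.2.0, SAMtools 1.10 and featureCounts 2.0.0 were used with the hg38 genome. Per the file headers, counts were made by featureCounts from exons grouped by gene identifier in the UCSC hg38 annotation, with read pairs counted as fragments and reverse strandedness. Neither multiply mapped reads nor reads that overlap several genes were counted, per the file headers, so genes with near-identical copies or shared exons can lose reads. Read trimming, quality filters and duplicate removal are not given in the sources used here. Coordinates are those in the deposited count table (hg38, 1-based). The table held 26485 genes, all named by symbol, of which 4943 had 0 counts in every library. Of all genes 1141 were listed on an alternate or random contig, 391 of them among the genes tested, and 357 shared all coordinates with another gene.

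Library totals ran from 10879287 to 19106827 counts. A count of 0 in 1 library allows up to 3 counts, or 0.157 to 0.276 counts-per-million (CPM) depending on the library. A fold against a group with no counts was computed against 3 counts over the group and is given as a lower bound, and with 1 to 3 counts the ratio is given with an exact 95% interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicate libraries were compared by a chi-square test of their counts over genes, and in every group they differed by more than sampling noise (chi-square per degree of freedom 5.53 to 15.0), so no pair was taken for 1 library deposited again. This cannot tell separate cultures from repeat preparations of 1 culture.

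The choices named in this paragraph and the next were made before the data were examined, apart from the alternatives named as later ones. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (16149 genes tested), libraries were scaled by TMM, and quasi-likelihood F-tests (glmQLFit, glmQLFTest) were made from 1 fit of all 14 libraries with 1 mean per group and no further covariate, which left 7 residual degrees of freedom. The common biological coefficient of variation was 0.101. The 9 contrasts were low Wnt and high Wnt each against hESC, high Wnt against low Wnt, SB4 and TGFB each against no additive at both doses, and for each additive the difference of its effects between doses. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The principal components used log2 CPM with a prior count of 2.

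Fixed gene lists, 29 in number, covered pluripotency, neural plate border, neural crest specifiers, anterior identity, HOX paralogues 1 to 5, 6 to 9 and 10 to 13, axial progenitors, ectomesenchyme and pharyngeal arch, sensory and autonomic neurons, melanocytes, Schwann cells and glia, central nervous system progenitors, surface ectoderm and placodes, mesoderm, endoderm, endothelium and blood, TGF-beta and SMAD2/3 targets, BMP and SMAD1/5 targets, Wnt and beta-catenin targets, retinoic acid response, FGF and ERK response, Notch targets, extracellular matrix, smooth muscle contractile genes, epithelial state, mesenchymal state, cell cycle, and stress and p53 response. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over 252 tests, and again with an estimated correlation. HOX paralogues 10 to 13 had 2 tested members and are described by gene. Named genes were, per contrast, the 5 largest and 5 smallest log2 fold changes among called genes with protein-coding-style symbols, a mean of at least 10 CPM in the higher group and groups that did not overlap, up to 4 members with the smallest p of each list described, and a fixed panel of stem cell, crest, axial and signaling genes. For the differences between doses the condition on overlap was left out. A few genes that this rule names are not reported here, though counts over lists and over all genes include them.

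The alternatives were DESeq2 1.42.0, RLE scaling, library totals alone, no filter, only the groups compared, the replicate number as a block, a log2 fold change of at least 1, and leaving out each library in turn. After the data were seen, a fit without the hESC libraries was added, and counts of genes for SB4 and for TGFB in low Wnt without those higher in hESC than in high Wnt, and correlations between effects with each library left out in turn. Correlations between effects were computed only between contrasts with no library in common. The procedure was tested on simulated counts with known changes. For SB4 in low Wnt (16005 genes) it recovered 49.3% of 1.5-fold, 79.1% of 2-fold and 100% of 4-fold changes, with 6.75% false calls. For TGFB in high Wnt (15962 genes) the shares were 50.7%, 71.6% and 93.9%, and for the SB4 difference between doses (15987 genes) 13.4%, 50.7% and 87.9%. With no effect, 1 of 28 lists was called. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No sample was left out, and the reads themselves were not analysed here.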

Results

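Messenger RNA was measured by sequencing in WA01 cells (the human embryonic stem cell line also called H1) and in neural crest cultures induced from them. Induction lasted 5 days and used CHIR99021, an inhibitor of the kinase GSK3 that activates canonical Wnt signaling, during hours 0 to 72. The dose was 3 µM in the groups called low Wnt and 10 µM in the groups called high Wnt. At each dose some cultures also received, from hour 0 to hour 120, either SB431542 (SB4) at 10 µM, an inhibitor of the type I receptors for TGF-beta, activin and nodal, or TGF-beta 1 (TGFB) at 5 ng/µL as the labels state the dose. The 7 groups were uninduced cells (hESC), low Wnt, low Wnt + SB4, low Wnt + TGFB, high Wnt, high Wnt + SB4 and high Wnt + TGFB, with 2 libraries each and 14 in all. The gene counts of replicates 1 and 2 summed to 14174120 and 12930505 in hESC. They summed to 16654777 and 16764513 in low Wnt, 16466496 and 19106827 in low Wnt + SB4, and 13452564 and 16167956 in low Wnt + TGFB. In the groups with the higher dose they summed to 12396451 and 14634002 without additive, 15496210 and 17424753 with SB4, and 10879287 and 15903635 with TGFB. Levels are counts-per-million (CPM) given as mean ± SD over the 2 libraries of a group, and fold changes are log2 values with their standard errors (SE). The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. All 14 libraries shared 1 estimate of that spread, and adjusted p values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

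The 2 libraries of a group had a correlation of log2 CPM across genes of 0.988 to 0.992. The first principal component held 51.8% of the variance and the second 26.6%. On the first component hESC lay at 154 and 163 and low Wnt at -1.57 and 1.36. The 6 libraries of the high Wnt groups lay between -68.0 and -62.4. High Wnt was not set apart from high Wnt + TGFB on these 2 components, and on the third (7.59%) lay at 3.40 and 4.10 against 17.8 and 13.1. The low Wnt + TGFB libraries lay between low Wnt and hESC on the first, at 46.0 and 58.3. On the third they lay past both, at 56.0 and 56.7. Their mean correlation with the hESC libraries was 0.902, against 0.842 for low Wnt, 0.82 for low Wnt + SB4, 0.806 for high Wnt, 0.807 for high Wnt + SB4 and 0.801 for high Wnt + TGFB.

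**Figure D1:**
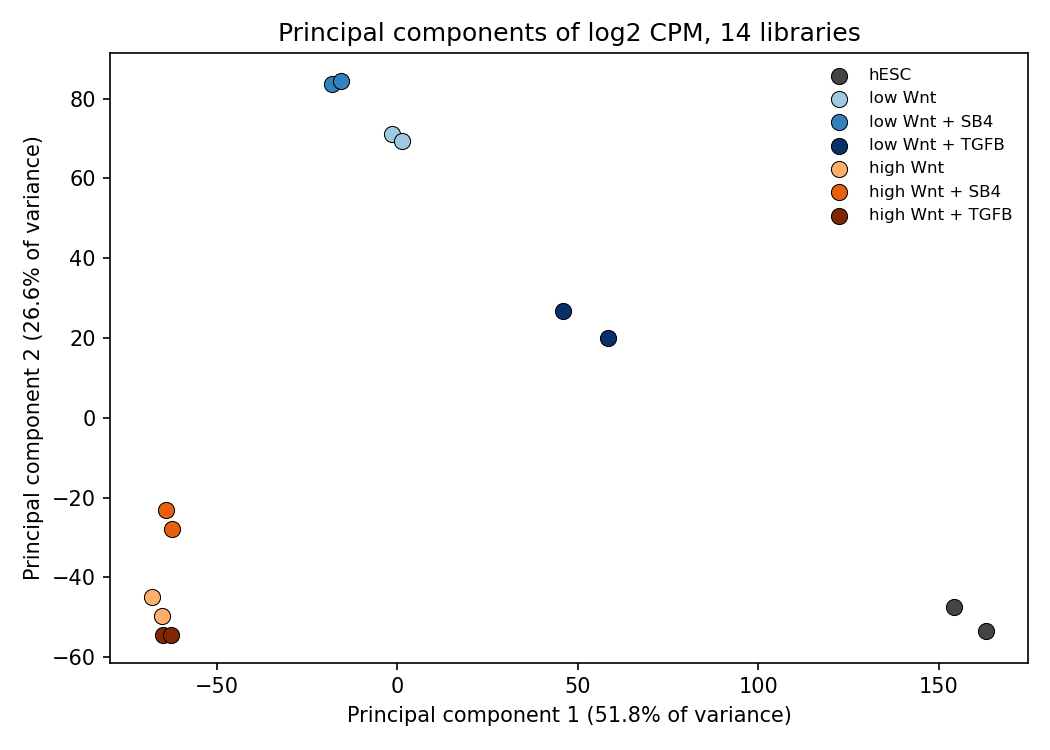
Position of the 14 libraries on the first (51.8% of variance) and second (26.6%) principal components of log2 CPM, one colour per group. Low Wnt + TGFB lies between low Wnt and hESC on the first component, at 46.0 and 58.3, but not on the third.

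The comparison of low Wnt with hESC asked what changed when the stem cells were induced with the lower dose of CHIR99021. The stem cell transcription factors NANOG (chromosome 12, 7789396 to 7796061, hg38) and POU5F1, also listed on alternate contigs, fell from 87.1 ± 9.11 to 1.2 ± 0.667 CPM and from 198 ± 47.5 to 3.16 ± 1.71 CPM (SD, n = 2), with log2 fold changes of -6.16 ± 0.276 and -5.96 ± 0.286 (SE). SOX2, which marks neural progenitors as well as stem cells, stood at 493 ± 72.0 against 380 ± 4.76 CPM (adjusted p = 0.00982, and 0.163 without low Wnt replicate 1). Epithelial cadherin CDH1 (chromosome 16, 68737292 to 68835541) fell from 340 ± 17 to 11.4 ± 1.60 CPM, and the neural cadherin CDH2 rose from 106 ± 2.93 to 549 ± 35.5 CPM. Among genes with at least 10 CPM, the 5 largest rises were in NR2F2, an orphan nuclear receptor of the COUP-TF family, MMRN1, which encodes multimerin 1, HOXA2, the hindbrain and pharyngeal arch HOX gene, NTRK2, the receptor for the neurotrophin BDNF, and GREB1L. NTRK2 stood at 569 ± 6.00 against 0.233 ± 0.0894 CPM (log2 fold change 11.18 ± 0.296). NR2F2 had 348 ± 44.5 CPM against 1 count over both hESC libraries (ratio 8790, 95% counting interval 1580 to 347000), and GREB1L had 211 ± 2.79 CPM against 3 counts (ratio 1780, interval 610 to 8640). MMRN1 and HOXA2 had no counts in hESC and were at least 477-fold and at least 233-fold higher, taking 3 counts over the group as the floor. Of the 5 largest falls, 4 were in D21S2088E, TIMP4, a metalloproteinase inhibitor, LCK, a tyrosine kinase best known from T cells, and NKX1-2, a homeobox gene of the caudal epiblast. D21S2088E and TIMP4 had no counts in low Wnt and were at least 371-fold and 121-fold lower, LCK changed by -9.28 ± 0.385, and NKX1-2 had 1 count in low Wnt (ratio 529, interval 94.5 to 21000).

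By group, 1 of 18 pluripotency genes rose, 16 fell and 1 did not pass (list adjusted p = 3.68e-16). DNMT3B, the stem cell DNA methyltransferase, changed by -3.07 ± 0.0958 and TDGF1, a nodal co-receptor, by -6.29 ± 0.199. All 12 epithelial genes fell, among them the tight junction gene CLDN7 (-6.46 ± 0.215) and the adhesion gene EPCAM (-4.46 ± 0.191; list adjusted p = 3.68e-16). Of 11 mesenchymal genes 7 rose and 3 fell, led by the transcription factors ZEB2 (9.88 ± 0.233) and ZEB1 (7.79 ± 0.280) and the cadherin CDH11 (5.31 ± 0.132; list adjusted p = 5.6e-08). Of 12 retinoic acid response genes 8 rose and 3 fell, or 8 and 4 adjusted over the list alone, led by CYP26C1, which degrades retinoic acid, at 402 ± 28.8 against 0.249 ± 0.248 CPM, the cofactor MEIS2 (9.12 ± 0.221) and the receptor RARB (8.41 ± 0.293; list adjusted p = 3.05e-07). Those 4 lists kept their call with an estimated correlation between genes. Of 14 FGF and ERK response genes 11 fell and 3 rose, with ETV4 (-5.93 ± 0.191) and SPRY4 (-5.22 ± 0.232) as examples (list adjusted p = 3.17e-06, adjusted p = 0.0713 with an estimated correlation). Of 12 progenitor genes of the central nervous system 8 rose and 1 fell, including SOX1 (8.92 ± 0.258) and PAX6 (6.75 ± 0.310), and the list median of 4.86 became 3.33 with genes near 0 counts at their bounds (adjusted p = 0.000663, adjusted p = 0.149 with an estimated correlation). Of 17 stress and p53 response genes 9 fell and 3 rose (adjusted p = 0.0039, adjusted p = 0.0713 with an estimated correlation). PMAIP1 changed by -4.54 ± 0.136 and ASNS by -2.41 ± 0.102. Of the 15 HOX genes of paralogue groups 1 to 5, 11 rose and 4 did not pass, and the median of 5.09 became 3.36 at the bounds (adjusted p = 0.01, adjusted p = 0.313 with an estimated correlation). Among neural crest specifiers 10 of 18 rose and 3 fell (list adjusted p = 0.142). SNAI2, which drives the epithelial to mesenchymal transition, rose from 0.868 ± 0.0282 to 18.4 ± 0.828 CPM, and the early crest factor TFAP2A rose from 0.153 ± 0.0970 to 3.50 ± 0.472 CPM. FOXD3, active in stem cells and early crest, fell from 36.5 ± 6.37 to 0.516 ± 0.476 CPM, and SOX10 stood at 5.64 ± 1.27 and 4.05 ± 0.309 CPM (adjusted p = 0.142). The Wnt target LEF1 rose by 3.80 ± 0.215 and AXIN2 by 0.97 ± 0.144. In all, 11535 of the 16149 genes tested passed an adjusted p of 0.05, 5780 higher and 5755 lower, and 6550 of them changed by at least 1 on the log2 scale.

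The comparison of high Wnt with hESC asked what the higher dose of CHIR99021 changed. Among genes with at least 10 CPM, the 5 largest rises were in HOX genes, which set position along the body axis. HOXB9 (chromosome 17, 48621157 to 48626473, hg38), HOXB3, HOXD4, HOXC4 and HOXC6 stood at 920 ± 69.7, 558 ± 74.2, 303 ± 9.0, 275 ± 35.9 and 229 ± 37.0 CPM in high Wnt (SD, n = 2) and had no counts in hESC, which made them at least 7790-fold, 4740-fold, 2560-fold, 2340-fold and 1950-fold higher. HOXC4 and HOXC6 are annotated from the same start on chromosome 12 (54016852, with ends at 54056030 and 54030823) and share exons, so the division of reads between them is uncertain. CDX2, a caudal homeobox gene of the tail end of the embryo, stood at 318 ± 7.25 CPM against 2 counts over both hESC libraries (ratio 4010, counting interval 1110 to 33100). TBXT, the brachyury gene of primitive streak and tailbud, rose from 0.540 ± 0.283 to 51.4 ± 6.59 CPM (log2 fold change 6.52 ± 0.264 SE), and PAX3, a paired box gene of dorsal neural tube and crest, stood at 173 ± 6.05 CPM against 2 counts (ratio 2180, interval 604 to 18000). NANOG had no counts in high Wnt and was at least 767-fold lower. TRIML2, MARVELD3, a tight junction protein, LAD1, a basement membrane anchoring protein, and GRHL2, a transcription factor of epithelia, also had no counts in high Wnt and were at least 534-fold, 465-fold, 425-fold and 409-fold lower. CDH1 fell by 9.53 ± 0.245 on the log2 scale, while SOX2 stood at 320 ± 41.6 against 380 ± 4.76 CPM (adjusted p = 0.0735).

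All 15 HOX genes of paralogue groups 1 to 5 and all 12 of groups 6 to 9 rose, with list medians of 9.54 and 8.15 once genes near 0 counts were set at their bounds (list adjusted p = 7.98e-30 and 1.82e-18). Of 15 axial progenitor genes 13 rose and 1 fell, including CDX1 (ratio 953, interval 171 to 37700) and the ligand WNT3A (7.96 ± 0.305; list adjusted p = 1.39e-11). Of 18 pluripotency genes 16 fell and 1 rose, with TDGF1 at 0.269 ± 0.0892 against 1078 ± 9.36 CPM (list adjusted p = 3.01e-24). All 12 epithelial genes fell and all 11 mesenchymal genes rose (list adjusted p = 4.58e-16 and 8.72e-14). The splicing factor ESRP1 changed by -7.20 ± 0.284, ZEB1 by 9.23 ± 0.259 and SNAI2 by 5.57 ± 0.265. Of 12 retinoic acid response genes 11 rose and 1 fell, among them MEIS1 (7.27 ± 0.207) and CRABP2, a retinoic acid carrier (3.27 ± 0.115; list adjusted p = 5.26e-10). These 7 lists kept their call with an estimated correlation between genes, and the next 6 lost it. Of 19 extracellular matrix genes 15 rose and 3 fell (list adjusted p = 2.87e-07, adjusted p = 0.0632 with an estimated correlation). The proteoglycan BGN changed by 5.58 ± 0.139 and the collagen COL3A1 by 6.74 ± 0.292. Of 18 Wnt targets 12 rose and 4 fell, or 13 and 4 adjusted over the list alone (list adjusted p = 4.09e-05, adjusted p = 0.0713 with an estimated correlation). LEF1 rose by 8.14 ± 0.180, SP5 by 4.77 ± 0.376 and TNFRSF19 by 6.21 ± 0.174, and AXIN2 stood at 45.7 ± 4.28 against 36.5 ± 0.959 CPM (adjusted p = 0.0587). Of 11 neural plate border genes 8 rose and 1 fell (list adjusted p = 0.000108, adjusted p = 0.172 with an estimated correlation). MSX1 changed by 8.74 ± 0.479 and ZIC1 by 4.75 ± 0.231. Of 15 mesoderm genes 10 rose and 2 fell (list adjusted p = 0.00265, adjusted p = 0.217 with an estimated correlation). FOXC1 changed by 7.15 ± 0.285 and the VEGF receptor KDR by -6.28 ± 0.174. Of 14 BMP targets 11 rose and 3 fell, GREM1, a BMP antagonist also listed on another contig, by 6.42 ± 0.340 (list adjusted p = 0.0104, adjusted p = 0.319 with an estimated correlation). Among 27 TGF-beta and SMAD2/3 targets 15 rose and 7 fell (list adjusted p = 0.0143, adjusted p = 0.143 with an estimated correlation). TGFBI, a matrix protein induced by TGF-beta, stood at 403 ± 47.7 against 13.3 ± 1.5 CPM, and LEFTY2, a feedback inhibitor of nodal, at 159 ± 35.7 against 7.26 ± 1.26 CPM. The smooth muscle actin gene ACTA2 rose by 5.88 ± 0.161, while the 12 contractile genes as a list, with 7 higher and 4 lower, gave an adjusted p of 0.086. Of 18 neural crest specifiers 9 rose and 5 fell (list adjusted p = 0.156), TWIST1 by 4.99 ± 0.393. In all, 11692 genes passed an adjusted p of 0.05, 5863 higher and 5829 lower, and 6973 of them changed by at least 1 on the log2 scale.

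**Figure D2:**
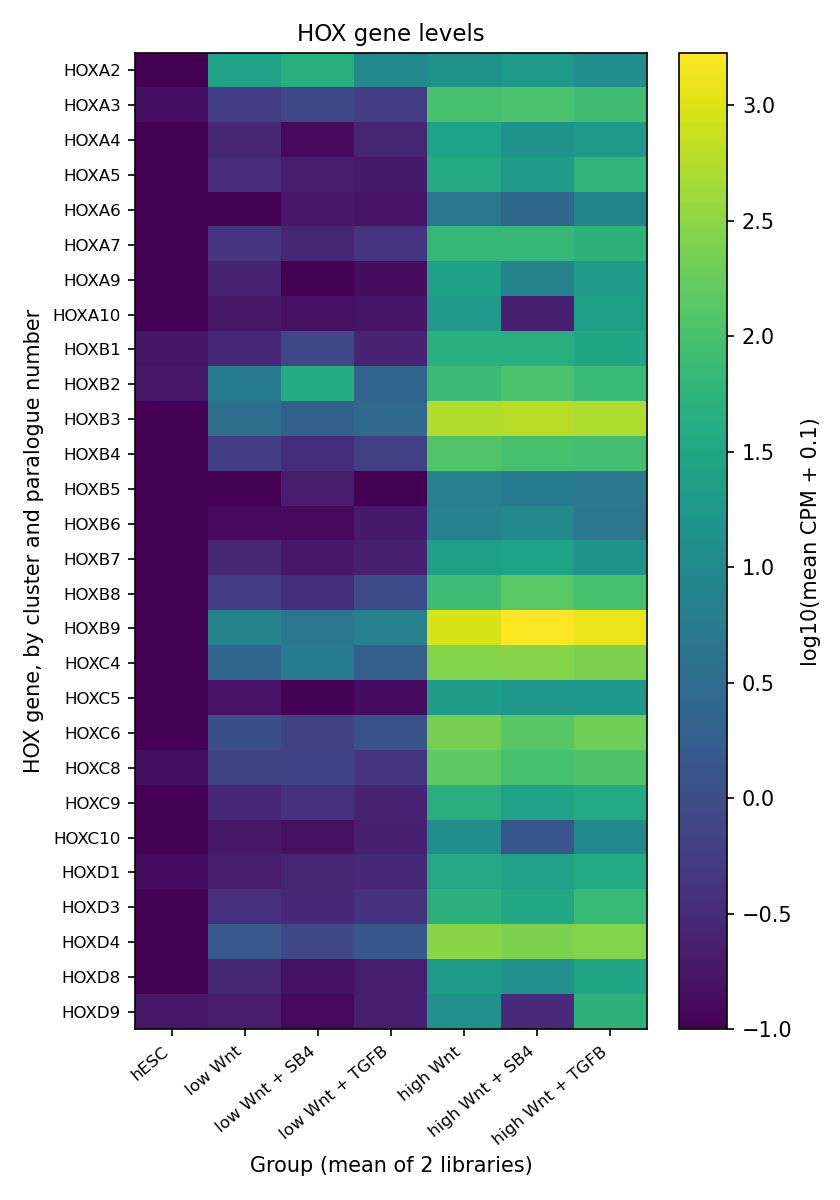
Levels of 28 HOX genes in the 7 groups, drawn as log10 of the mean CPM over 2 libraries plus 0.1, with genes ordered by cluster and paralogue group. Genes such as HOXB9 (920 CPM in high Wnt) are high in the 3 groups with 10 µM CHIR99021, and HOXA2 is high at both doses (27.6 CPM in low Wnt and 14.6 CPM in high Wnt).

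The comparison of high Wnt with low Wnt asked what the dose of CHIR99021 changed among induced cells. HOX genes of paralogue groups 1 to 5 (14 of 15) and 6 to 9 (12 of 12) and axial progenitor genes (13 of 15) were higher, and pluripotency genes (13 of 18) lower. TBXT (chromosome 6, 166157656 to 166168669, hg38) stood at 51.4 ± 6.59 CPM in high Wnt and 0.180 ± 0.0830 CPM in low Wnt (SD, n = 2; log2 fold change 8.08 ± 0.297 SE). CDX2 (chromosome 13, 27962068 to 27969368) stood at 318 ± 7.25 and 1.42 ± 0.366 CPM, HOXD1 at 35.4 ± 1.77 and 0.121 ± 0.00157 CPM, and HOXC6 at 229 ± 37.0 and 0.935 ± 0.0305 CPM. UNCX, a homeobox gene of the somites, had 12.6 ± 2.22 CPM in high Wnt and no counts in low Wnt (at least 138-fold higher), and HOXC5, which shares exons with HOXC4 and HOXC6, had 2 counts in low Wnt (ratio 375, counting interval 103 to 3110). SOX1, a marker of the early neural plate, fell from 176 ± 0.371 to 1.16 ± 0.697 CPM, and OTX2, the forebrain and midbrain homeobox gene (chromosome 14, 56800707 to 56810476), from 18.5 ± 2.83 to 0.394 ± 0.265 CPM. DBX1, a homeobox gene of spinal and hindbrain progenitors, had 13.6 ± 0.432 CPM in low Wnt and no counts in high Wnt (at least 120-fold lower). CYP26C1 (-8.78 ± 0.213), the matrix protein gene PAPLN (-7.91 ± 0.236) and the neuronal pentraxin gene NPTX1 (-7.87 ± 0.284) were the other large falls.

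Of the 15 HOX genes of paralogue groups 1 to 5, 14 were higher in high Wnt and 1 was lower, and all 12 of groups 6 to 9 were higher (list adjusted p = 1.12e-63 and 1.48e-47). The gene that was lower, HOXA2, had a log2 fold change of -0.92 ± 0.194. Of 15 axial progenitor genes 13 were higher and 1 lower, including FGF17 (7.73 ± 0.351) and CDX1 (6.56 ± 0.243; list adjusted p = 7.93e-20). Of 14 FGF and ERK response genes 10 were higher and 2 lower (list adjusted p = 8.75e-16). ETV5 changed by 3.70 ± 0.124 and the feedback regulator SPRY2 by 3.36 ± 0.161. Of 15 mesoderm genes 13 were higher and 1 lower, with the somite genes MEOX1 (7.06 ± 0.288) and FOXC1 (6.17 ± 0.242) as examples (list adjusted p = 4.74e-14). Of 19 extracellular matrix genes 14 were higher and 2 lower, or 14 and 3 adjusted over the list alone (list adjusted p = 4.66e-14). BGN changed by 4.68 ± 0.124 and COL5A2 by 2.07 ± 0.108. COL1A1, the chief fibrillar collagen, stood at 510 ± 5.96 against 262 ± 11.4 CPM. Of 27 TGF-beta and SMAD2/3 targets 20 were higher and 2 lower (list adjusted p = 4.02e-09). TGFBI changed by 6.02 ± 0.176 and LEFTY2 by 5.97 ± 0.224, while the latent TGF-beta binding protein gene LTBP2 by -2.97 ± 0.181 and the metalloproteinase inhibitor TIMP3 by -1.89 ± 0.120. Of 18 Wnt targets 10 were higher and 3 lower (list adjusted p = 1.08e-06). LEF1 stood at 270 ± 32.6 against 13.3 ± 0.856 CPM and SP5 at 21.9 ± 1.85 against 1.66 ± 0.448 CPM, while AXIN2 was lower at the higher dose, at 45.7 ± 4.28 against 71.6 ± 10.2 CPM (adjusted p = 0.00152). Among 18 pluripotency genes 13 were lower and 1 higher, with TDGF1 at 0.269 ± 0.0892 against 13.7 ± 5.20 CPM (list adjusted p = 1.07e-09). These 9 lists kept their call with an estimated correlation.

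A further 6 lists passed at the preset correlation only. Of 11 neural plate border genes 7 were higher and 2 lower, or 8 and 2 adjusted over the list alone (list adjusted p = 7.58e-08, adjusted p = 0.0713 with an estimated correlation). PAX3 changed by 4.51 ± 0.138 and ZIC1 by 6.24 ± 0.258. Of 12 central nervous system genes 7 were lower and 2 higher, or 9 and 2 adjusted over the list alone (list adjusted p = 1.2e-07, adjusted p = 0.0518 with an estimated correlation). PAX6 changed by -3.03 ± 0.204 and OLIG3 by -5.41 ± 0.367. Of 11 mesenchymal genes 7 were higher and 2 lower (list adjusted p = 0.000302, adjusted p = 0.0713 with an estimated correlation). Of 12 smooth muscle contractile genes 8 were higher and 3 lower (list adjusted p = 0.00154, adjusted p = 0.216 with an estimated correlation). ACTA2 changed by 2.81 ± 0.123, TAGLN, the actin-binding protein SM22, by 2.34 ± 0.173 and TPM1 by -1.5 ± 0.110. Of 12 surface ectoderm and placode genes 7 were higher and 3 lower, with KRT18 at 2.14 ± 0.150, and the list mean of -0.09 differed in sign from its median of 1.00 and from its test (list adjusted p = 0.00167, adjusted p = 0.157 with an estimated correlation). Of 8 genes of anterior identity 5 were lower, with LHX5 at 1 count in high Wnt (ratio 83.4, interval 14.6 to 3320; list adjusted p = 0.00288, adjusted p = 0.0562 with an estimated correlation). The neural crest specifiers went both ways, with 6 of 18 higher and 7 lower (list adjusted p = 0.708, with a test that pointed up while the median was -0.04 and the mean -0.44). TWIST1 was higher by 4.80 ± 0.362 and SNAI2 by 1.18 ± 0.170, while SOX10 (-1.38 ± 0.320) was lower and TFAP2A lower with 3 counts in high Wnt (ratio 31, interval 10.3 to 153). In all, 6223 genes passed an adjusted p of 0.05, 3137 higher and 3086 lower, and 2774 of them changed by at least 1 on the log2 scale.

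**Figure D3:**
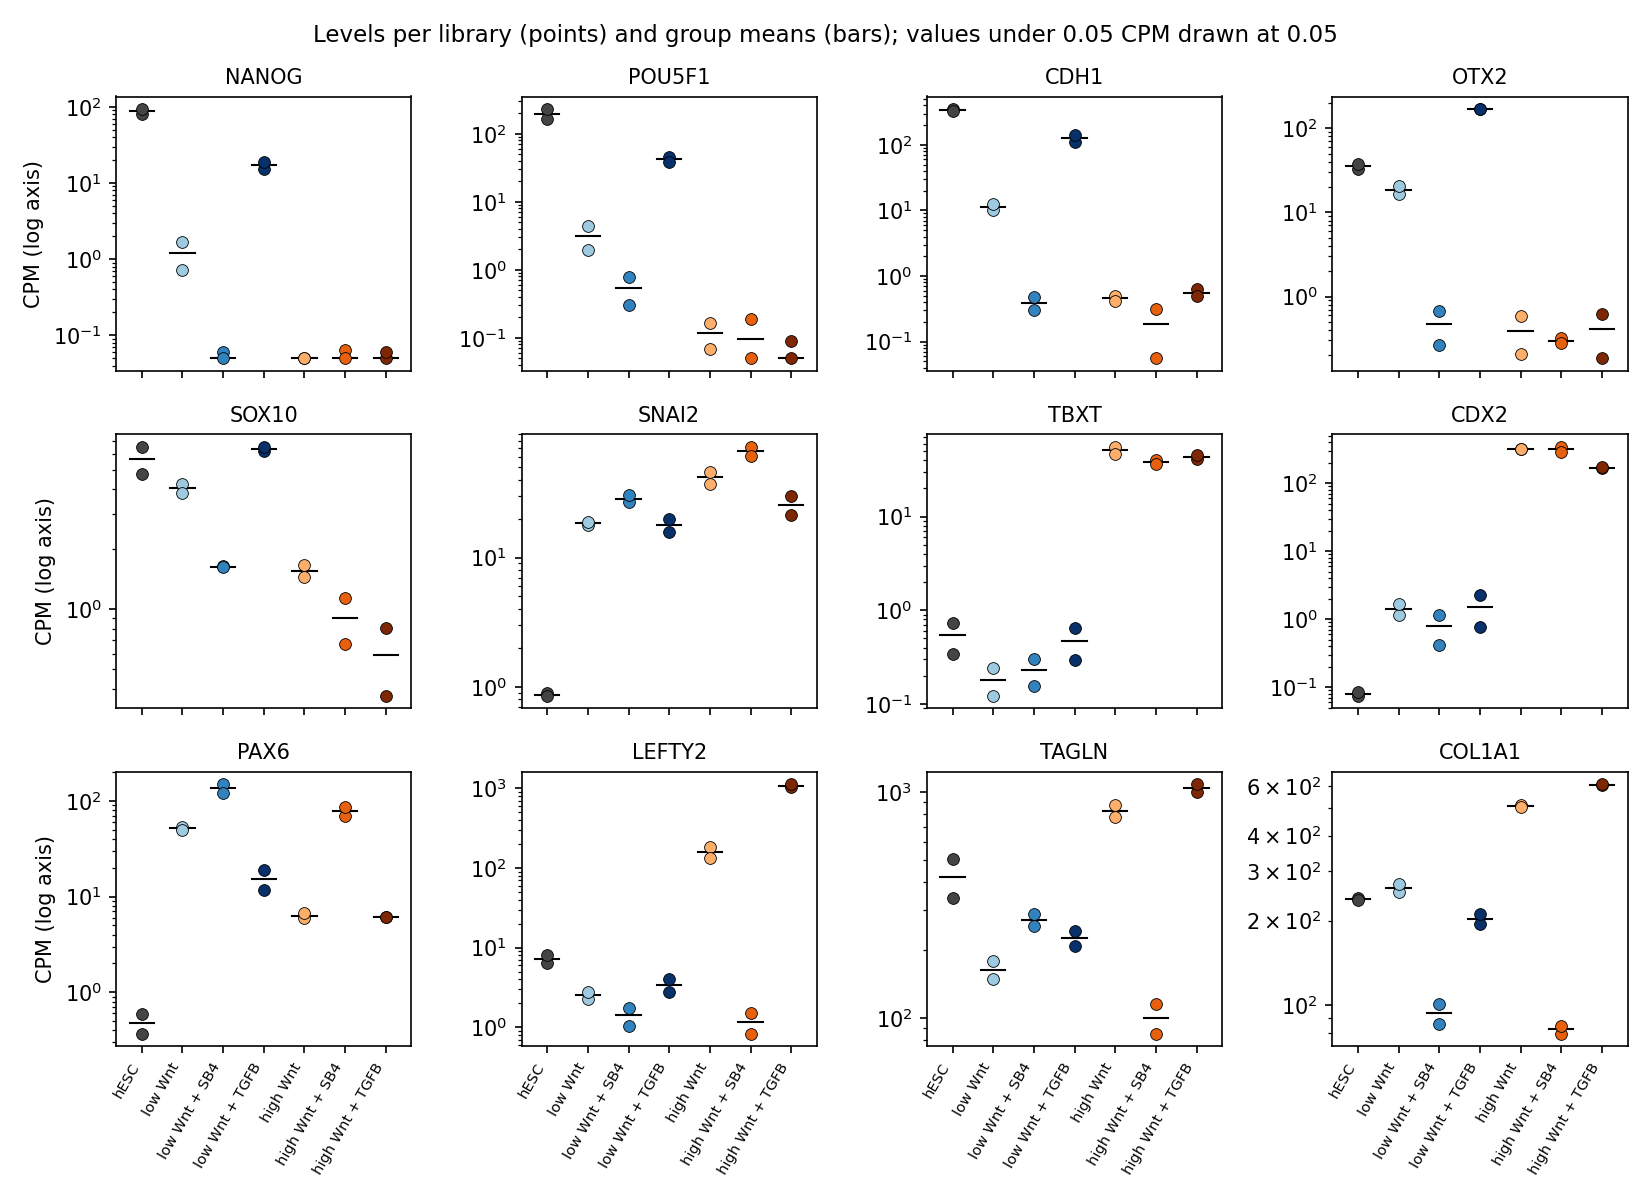
CPM of 12 genes on a log axis, with points for the 14 libraries and bars at the group means (n = 2); values under 0.05 CPM are drawn at 0.05. NANOG falls from 87.1 CPM in hESC to 1.20 CPM in low Wnt and stands at 17.1 CPM in low Wnt + TGFB, and TAGLN falls from 826 to 100 CPM when SB4 is added in high Wnt.

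SB4 was compared with no additive in low Wnt to ask which transcripts depended on TGF-beta, activin or nodal receptor activity at the lower dose. Genes of pluripotency (10 of 18), epithelium (9 of 12) and anterior identity (4 of 8) fell. OTX2 fell from 18.5 ± 2.83 to 0.466 ± 0.289 CPM (SD, n = 2; log2 fold change -5.33 ± 0.292 SE). TDGF1 fell from 13.7 ± 5.20 to 0.344 ± 0.116 CPM, CDH1 from 11.4 ± 1.60 to 0.388 ± 0.118 CPM, and ESRG, a transcript of pluripotent cells, from 84.3 ± 7.70 to 6.34 ± 0.599 CPM. PRDM14, a pluripotency regulator, had 11.4 ± 5.31 CPM in low Wnt and 3 counts with SB4 (ratio 136, counting interval 46.1 to 661). RGS5, a regulator of G protein signaling found in pericytes, rose from 32.9 ± 2.05 to 238 ± 11.1 CPM. HOXB2, a hindbrain HOX gene (chromosome 17, 48542656 to 48545031, hg38), rose from 5.70 ± 0.202 to 41.0 ± 8.98 CPM, the serine protease gene PRSS35 from 2.23 ± 0.398 to 18 ± 1.90 CPM, and MTTP, a lipid transfer protein, from 2.84 ± 0.293 to 19.4 ± 4.83 CPM. HES5, a Notch target also listed on an alternate contig, stood at 10.3 ± 11.3 against 1.21 ± 0.357 CPM (adjusted p = 0.0118). DESeq2 (0.221) and fits without low Wnt replicate 1 or 2 or low Wnt + SB4 replicate 2 did not make that call.

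Of 18 pluripotency genes 10 fell and none rose, or 12 adjusted over the list alone (list adjusted p = 5.12e-30). ZFP42, the stem cell zinc finger gene REX1, changed by -2.23 ± 0.171. The same libraries lay further from hESC in overall profile, with a mean correlation of 0.82 against 0.842 for low Wnt. Of 12 epithelial genes 9 fell and none rose (list adjusted p = 1.14e-25). EPCAM changed by -2.79 ± 0.259 and CLDN6 by -1.63 ± 0.134. Of 8 genes of anterior identity 4 fell and none rose, or 6 adjusted over the list alone (list adjusted p = 9.51e-11). LHX5 changed by -3.07 ± 0.426 and DMBX1 by -3.01 ± 0.493. These 3 lists kept their call with an estimated correlation. Of 12 central nervous system genes 7 rose and 1 fell (list adjusted p = 3.78e-06, adjusted p = 0.0699 with an estimated correlation). DBX1 changed by 1.84 ± 0.212, PAX6 by 1.38 ± 0.166 and IRX3 by 1.44 ± 0.181. Of 14 FGF and ERK response genes 4 fell, or 6 adjusted over the list alone (list adjusted p = 4.52e-05, adjusted p = 0.113 with an estimated correlation). PHLDA1 changed by -1.76 ± 0.146. Of 12 surface ectoderm and placode genes 4 fell, or 8 adjusted over the list alone, with GATA2 at 3 counts with SB4 (ratio 51.0, interval 17.1 to 250; list adjusted p = 0.000155, adjusted p = 0.101 with an estimated correlation). Of 14 BMP targets 4 fell, with ID2 at -0.68 ± 0.121 (list adjusted p = 0.00411, adjusted p = 0.267 with an estimated correlation), and of 15 mesoderm genes 4 fell (list adjusted p = 0.0103, adjusted p = 0.253 with an estimated correlation). KDR changed by -2.99 ± 0.290. Of 27 TGF-beta and SMAD2/3 targets 6 fell, 1 rose and 20 did not pass, or 8 fell and 3 rose adjusted over the list alone (list adjusted p = 0.019, adjusted p = 0.157 with an estimated correlation). The feedback regulator PMEPA1 fell by 3.76 ± 0.458, while CTGF, a matricellular protein gene also called CCN2, rose by 1.01 ± 0.140. Of the 15 HOX genes of paralogue groups 1 to 5, 3 rose, or 5 adjusted over the list alone (list adjusted p = 0.0201, adjusted p = 0.362 with an estimated correlation), and of 12 ectomesenchyme and pharyngeal arch genes 3 fell (list adjusted p = 0.0222, adjusted p = 0.225 with an estimated correlation). Of 12 contractile genes 3 were higher and 2 lower, or 4 and 2 adjusted over the list alone (list adjusted p = 0.189). COL1A1 fell from 262 ± 11.4 to 93.7 ± 11.1 CPM, and PAX3 rose from 7.61 ± 1.38 to 17.1 ± 0.412 CPM.

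In all, 1814 genes passed an adjusted p of 0.05 with SB4 in low Wnt, 782 higher and 1032 lower, and 711 of them changed by at least 1 on the log2 scale (202 higher, 509 lower). Without the genes that were higher in hESC than in high Wnt, an alternative chosen after the data were seen, 922 passed, 445 higher and 477 lower. Leaving out 1 of the compared libraries lowered the count each time.

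TGFB was compared with no additive in low Wnt to ask which transcripts the added ligand changed at the lower dose. Genes of pluripotency (13 of 18), epithelium (10 of 12), endoderm (12 of 12) and anterior identity (4 of 8) rose. NANOG rose from 1.20 ± 0.667 to 17.1 ± 2.42 CPM and POU5F1, listed on several contigs, from 3.16 ± 1.71 to 41.9 ± 4.21 CPM (SD, n = 2; log2 fold changes 3.82 ± 0.282 and 3.72 ± 0.282 SE). OTX2 rose from 18.5 ± 2.83 to 169 ± 1.61 CPM, and CDH1 from 11.4 ± 1.60 to 126 ± 22.7 CPM. The endoderm transcription factors SOX17 (chromosome 8, 54457935 to 54460896, hg38) and GATA4 rose from 0.360 ± 0.251 to 23.5 ± 12.6 CPM and from 0.271 ± 0.124 to 13.5 ± 7.91 CPM. Other large rises were in TBX3, a T-box gene (6.20 ± 0.529), S100A14, a calcium-binding protein of epithelia (6.15 ± 0.447), and EPSTI1, named for epithelial and stromal interaction (5.45 ± 0.366). The growth factor gene IGF2 fell from 10.9 ± 0.995 to 0.506 ± 0.112 CPM, and the adhesion gene VCAM1 (chromosome 1, 100719640 to 100739046) from 12.6 ± 0.348 to 0.872 ± 0.0742 CPM. ATP2C2, a calcium pump, fell from 15.5 ± 0.841 to 1.40 ± 0.171 CPM, and the Notch ligand DLL1, also listed on an alternate contig, from 17.6 ± 6.20 to 1.84 ± 0.292 CPM. NDE1, a centrosomal protein gene also listed on an alternate contig, stood at 18.6 ± 22.5 against 1.31 ± 0.139 CPM (adjusted p = 0.00851, 0.496 without low Wnt replicate 2 and 0.0635 without low Wnt + TGFB replicate 2).

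Of 12 epithelial genes 10 rose and none fell, or 12 adjusted over the list alone (list adjusted p = 1.13e-29). CLDN7 changed by 4.04 ± 0.217 and EPCAM by 3.30 ± 0.185. Among 18 pluripotency genes 13 rose and 1 fell, or 15 and 1 adjusted over the list alone (list adjusted p = 2.46e-25). TDGF1 changed by 3.99 ± 0.184 and L1TD1 by 3.30 ± 0.178. The low Wnt + TGFB libraries had a mean correlation of 0.902 with the hESC libraries, against 0.842 for low Wnt. All 12 endoderm genes rose, including FOXA2 (4.40 ± 0.447) and APOA1 (4.62 ± 0.501; list adjusted p = 7.58e-14). Of 14 FGF and ERK response genes 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (list adjusted p = 1.76e-12). SPRY4 changed by 2.98 ± 0.230 and ETV4 by 2.90 ± 0.191. Of 8 genes of anterior identity 4 rose and 1 fell, or 6 and 1 adjusted over the list alone (list adjusted p = 1.77e-06). DMBX1 changed by 3.50 ± 0.306 and LHX5 by 2.71 ± 0.300. These 5 lists kept their call with an estimated correlation, and the next 11 lost it. Of 12 central nervous system genes 8 fell and 2 rose, or 8 and 3 adjusted over the list alone (list adjusted p = 1.36e-06, adjusted p = 0.0538 with an estimated correlation). SOX1 changed by -2.14 ± 0.140 and PAX6 by -1.77 ± 0.181. Of 14 BMP targets 8 rose (list adjusted p = 9.85e-05, adjusted p = 0.19 with an estimated correlation). Of 18 Wnt targets 7 rose and 1 fell, or 7 and 2 adjusted over the list alone, with the Wnt antagonist DKK1 at 3.70 ± 0.211 and SP5 at 4.66 ± 0.312 (list adjusted p = 0.000386, adjusted p = 0.0816 with an estimated correlation). Of 11 neural plate border genes 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (list adjusted p = 0.00231, adjusted p = 0.267 with an estimated correlation). Of 12 surface ectoderm and placode genes 6 rose and 1 fell, or 7 and 2 adjusted over the list alone (list adjusted p = 0.0031, adjusted p = 0.201 with an estimated correlation). KRT18 changed by 2.16 ± 0.150. Of 27 TGF-beta and SMAD2/3 targets 12 rose and 2 fell, or 14 and 2 adjusted over the list alone (list adjusted p = 0.0046, adjusted p = 0.142 with an estimated correlation). NODAL had 7.07 ± 0.847 CPM against 3 counts in low Wnt (ratio 78.8, counting interval 26.6 to 385), and the SMAD regulators SKIL and SMAD7 rose by 2.13 ± 0.202 and 1.57 ± 0.290, while TIMP3 fell by 1.94 ± 0.120.

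Of 17 stress and p53 response genes 8 rose and 1 fell (list adjusted p = 0.00612, adjusted p = 0.0777 with an estimated correlation). The p53 target PMAIP1 changed by 4.23 ± 0.135. Of 10 Notch targets 6 fell and 2 rose (list adjusted p = 0.00827, adjusted p = 0.244 with an estimated correlation). DLL3 changed by -2.06 ± 0.174. Of 20 cell cycle genes 10 fell and 2 rose, or 11 and 2 adjusted over the list alone (list adjusted p = 0.0119, adjusted p = 0.263 with an estimated correlation). Of 15 mesoderm genes 3 rose (list adjusted p = 0.0375, adjusted p = 0.313 with an estimated correlation). KDR changed by 3.38 ± 0.159 and the mesendoderm factor EOMES by 5.21 ± 0.610. Of 12 retinoic acid response genes 5 fell and 2 rose (list adjusted p = 0.0447, adjusted p = 0.267 with an estimated correlation). In all, 4196 genes passed an adjusted p of 0.05 with TGFB in low Wnt, 2220 higher and 1976 lower (52.9% higher), and 1654 of them changed by at least 1 on the log2 scale (1199 higher, 455 lower). With library totals as the only scaling, 2787 were higher and 1383 lower (66.8% higher). Without the genes that were higher in hESC than in high Wnt, 2239 passed, 551 higher and 1688 lower. Leaving out 1 of the compared libraries lowered the count each time.

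SB4 in high Wnt asked the same of receptor activity at the higher dose. Targets of TGF-beta and SMAD2/3 (22 of 27), contractile genes (10 of 12) and matrix genes (11 of 19) fell. LEFTY2 (chromosome 1, 225936598 to 225941383, hg38) fell from 159 ± 35.7 to 1.18 ± 0.487 CPM (SD, n = 2; log2 fold change -7.09 ± 0.249 SE). The posterior HOX gene HOXA10 (chromosome 7, 27170591 to 27180261) fell from 19.5 ± 2.14 to 0.139 ± 0.197 CPM, and HOXD9 from 13.6 ± 0.106 to 0.218 ± 0.230 CPM. JPH2, which couples membranes in muscle cells, fell from 15.9 ± 1.53 to 0.787 ± 0.305 CPM, and PAPPA, a protease that frees insulin-like growth factors, from 28.9 ± 4.13 to 1.46 ± 0.621 CPM. TAGLN (chromosome 11, 117199324 to 117204792) fell from 826 ± 69.9 to 100 ± 21.0 CPM and COL1A1 from 510 ± 5.96 to 82.2 ± 3.76 CPM. PCDH8, a protocadherin, rose from 8.0 ± 0.742 to 115 ± 7.37 CPM. PAX6, a neural progenitor gene (chromosome 11, 31784792 to 31817961), rose from 6.33 ± 0.486 to 78.8 ± 12.4 CPM, and GDF10, a ligand of the TGF-beta family, from 11.7 ± 1.90 to 100 ± 5.25 CPM. ONECUT2, a homeobox gene of neurons and endoderm, rose from 11.1 ± 4.38 to 92.4 ± 31.9 CPM, and the ubiquitin ligase gene MARCH4 from 2.0 ± 1.17 to 15.3 ± 0.215 CPM.

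Of 27 TGF-beta and SMAD2/3 targets 22 fell, none rose and 5 did not pass, or 22 fell and 1 rose adjusted over the list alone (list adjusted p = 2.14e-26). LEFTY1 changed by -5.51 ± 0.459, TGFB1 by -2.58 ± 0.179 and SMAD7 by -1.35 ± 0.278. Of 12 contractile genes 10 fell and 1 rose, or 11 and 1 adjusted over the list alone (list adjusted p = 1.4e-24). TAGLN changed by -3.04 ± 0.179, calponin CNN1 by -2.01 ± 0.134, ACTA2 by -1.90 ± 0.117 and the myosin light chain gene MYL9 by -1.68 ± 0.124. Of 19 extracellular matrix genes 11 fell and 1 rose, or 13 and 1 adjusted over the list alone (list adjusted p = 2.22e-14). COL1A1 changed by -2.63 ± 0.101, BGN by -1.75 ± 0.102 and LOX, which crosslinks collagen, by -1.76 ± 0.193. These 3 lists kept their call with an estimated correlation, and the next 9 lost it. Of 12 epithelial genes 9 fell (list adjusted p = 8.27e-07, adjusted p = 0.172 with an estimated correlation). Of 12 central nervous system genes 5 rose and none fell (list adjusted p = 1.89e-06, adjusted p = 0.069 with an estimated correlation). IRX3 changed by 1.32 ± 0.185 and SOX1 by 1.71 ± 0.298. Of 15 mesoderm genes 10 fell and 1 rose, or 12 and 1 adjusted over the list alone (list adjusted p = 2.76e-06, adjusted p = 0.0698 with an estimated correlation). TBX6 changed by -1.79 ± 0.203 and the gene that rose, MEOX2, by 2.96 ± 0.495. Of 11 neural plate border genes 7 rose (list adjusted p = 0.000811, adjusted p = 0.225 with an estimated correlation). Of 12 HOX genes of paralogue groups 6 to 9, 5 fell and 1 rose, or 7 and 2 adjusted over the list alone (list adjusted p = 0.00265, adjusted p = 0.322 with an estimated correlation). HOXD9 and HOXA9 changed by -5.97 ± 0.390 and -1.72 ± 0.290, and HOXC9 by -0.74 ± 0.157. Of the 12 HOX genes of groups 10 to 13 only HOXA10 and HOXC10 had enough counts to be tested, and HOXC10 fell by 3.33 on the log2 scale, from 12.4 ± 2.77 to 1.23 ± 0.324 CPM (adjusted p = 2.64e-05). Of 17 stress and p53 response genes 7 fell, or 9 lower and 1 higher adjusted over the list alone (list adjusted p = 0.00299, adjusted p = 0.0698 with an estimated correlation). CDKN1A changed by -1.39 ± 0.211. Of 12 surface ectoderm and placode genes 5 fell (list adjusted p = 0.0253, adjusted p = 0.267 with an estimated correlation). Of 18 Wnt targets 7 fell and 3 rose, or 9 and 3 adjusted over the list alone (list adjusted p = 0.0282, adjusted p = 0.225 with an estimated correlation). DKK1 changed by -2.79 ± 0.188 and LEF1 by -0.63 ± 0.104. Of 20 cell cycle genes the replication genes MCM2 (0.88 ± 0.113), MCM3 (0.69 ± 0.0909), MCM5 (0.94 ± 0.124) and PCNA (0.67 ± 0.119) rose and 16 did not pass (list adjusted p = 0.0424, adjusted p = 0.337 with an estimated correlation).

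In all, 3476 genes passed an adjusted p of 0.05 with SB4 in high Wnt, 1605 higher and 1871 lower (46.2% higher), and 962 of them changed by at least 1 on the log2 scale (358 higher, 604 lower). With library totals as the only scaling, 2040 were higher and 1538 lower (57% higher). Leaving out 1 of the compared libraries lowered the count each time.

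TGFB in high Wnt asked what the added ligand changed at the higher dose. Mesoderm genes (8 of 15) rose, and genes of sensory and autonomic neurons (6 of 18) and axial progenitors (7 of 15) fell. FMOD, a collagen-binding proteoglycan, rose from 2.41 ± 2.23 to 55.9 ± 0.680 CPM (SD, n = 2; log2 fold change 4.48 ± 0.387 SE), and the nuclear receptor gene NR2F1 from 1.03 ± 0.191 to 12.6 ± 0.730 CPM. HAPLN1, which links hyaluronan to proteoglycans, rose from 15.5 ± 0.945 to 141 ± 4.11 CPM, and LEFTY2 from 159 ± 35.7 to 1072 ± 72.6 CPM. DDIT4L, an inhibitor of mTOR signaling, rose from 5.24 ± 0.365 to 32.4 ± 4.29 CPM. ONECUT2 fell from 11.1 ± 4.38 to 2.18 ± 0.216 CPM, and the neural progenitor gene SOX21 from 22.7 ± 3.63 to 4.76 ± 0.903 CPM. The noncoding RNA MIAT fell from 197 ± 26.1 to 51.7 ± 0.633 CPM, and FGF17 from 85.2 ± 22.7 to 23.8 ± 0.963 CPM. The neurogenic factor NEUROG2 fell from 13.8 ± 2.53 to 3.92 ± 1.23 CPM. SOX2 fell from 320 ± 41.6 to 156 ± 2.86 CPM and CDX2 from 318 ± 7.25 to 169 ± 4.26 CPM, and TWIST1, a crest and mesenchyme factor, rose from 7.80 ± 1.89 to 20.8 ± 1.85 CPM.

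Of 12 surface ectoderm and placode genes 6 rose and none fell, or 7 adjusted over the list alone, with EYA1, which muscle and mesoderm also use, at 2.0 ± 0.165 (list adjusted p = 1.47e-11). Of 15 mesoderm genes 8 rose and none fell, or 9 adjusted over the list alone (list adjusted p = 2.67e-09). MEOX1 changed by 1.59 ± 0.167, KDR by 1.83 ± 0.200, FOXC1 by 1.26 ± 0.149 and MEOX2 by 3.20 ± 0.496. Of 15 axial progenitor genes 7 fell and none rose, or 8 adjusted over the list alone (list adjusted p = 2.87e-07). Of 12 retinoic acid response genes 5 rose and 1 fell (list adjusted p = 1.4e-06). MEIS2 changed by 1.26 ± 0.120. Of 18 genes of sensory and autonomic neurons 6 fell and none rose, or 7 adjusted over the list alone (list adjusted p = 7.08e-06). Peripherin PRPH changed by -1.78 ± 0.216 and STMN2 by -1.28 ± 0.165. These 5 lists kept their call with an estimated correlation, and the next 6 lost it. Of 19 extracellular matrix genes 8 rose and 1 fell, or 10 and 3 adjusted over the list alone (list adjusted p = 1.12e-07, adjusted p = 0.0604 with an estimated correlation). COL1A2 changed by 1.21 ± 0.0933 and LOX by 1.79 ± 0.175. Of 20 cell cycle genes 2 fell, or 3 adjusted over the list alone (list adjusted p = 0.000101, adjusted p = 0.116 with an estimated correlation). Of 10 genes of Schwann cells and glia 4 fell, or 5 adjusted over the list alone (list adjusted p = 0.000278, adjusted p = 0.126 with an estimated correlation). Of 18 Wnt targets 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (list adjusted p = 0.00185, adjusted p = 0.111 with an estimated correlation). DKK1 changed by 2.0 ± 0.153. Among 27 TGF-beta and SMAD2/3 targets 5 rose, 3 fell and 19 did not pass, or 6 and 3 adjusted over the list alone (list adjusted p = 0.0119, adjusted p = 0.142 with an estimated correlation). LEFTY1 rose by 2.01 ± 0.254, TGFBI fell by 1.09 ± 0.133, and SMAD7 stood at 20.6 ± 3.49 against 17.1 ± 4.31 CPM (adjusted p = 0.641). Of 18 pluripotency genes 4 fell (list adjusted p = 0.0143, adjusted p = 0.267 with an estimated correlation).

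In all, 1170 genes passed an adjusted p of 0.05 with TGFB in high Wnt, 606 higher and 564 lower (51.8% higher), and 428 of them changed by at least 1 on the log2 scale (294 higher, 134 lower). With library totals as the only scaling, 787 were higher and 401 lower (66.2% higher), with DESeq2 574 were higher and 658 lower, and in the fit without the hESC libraries 730 and 791. Leaving out 1 of the compared libraries lowered the count each time.

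Whether the effect of each additive depended on the dose of CHIR99021 was tested as an interaction, the effect in high Wnt minus the effect in low Wnt. For SB4, contractile and TGF-beta target genes had a lower effect in high Wnt, and pluripotency and anterior genes a higher one. TAGLN stood at 163 ± 21.1 CPM in low Wnt and 272 ± 23.1 CPM with SB4, and at 826 ± 69.9 and 100 ± 21.0 CPM in high Wnt (SD, n = 2; difference of log2 fold changes -3.78 ± 0.243 SE). ACTC1, the cardiac actin gene, stood at 18.8 ± 5.35 and 35.3 ± 4.77 CPM in low Wnt and at 171 ± 42.6 and 10.8 ± 0.956 CPM in high Wnt. VCAM1 stood at 12.6 ± 0.348 and 66.8 ± 0.444 CPM in low Wnt and at 5.40 ± 0.237 and 0.795 ± 0.136 CPM in high Wnt (difference -5.15 ± 0.25). NPTX1 fell with SB4 in low Wnt, from 125 ± 5.88 to 10.7 ± 1.78 CPM, and stood at 0.517 ± 0.144 and 0.664 ± 0.229 CPM in high Wnt. Of 12 contractile genes 9 had a lower effect in high Wnt, or 10 lower and 1 higher adjusted over the list alone, and ACTA2 (-2.36 ± 0.168), CNN1 (-2.32 ± 0.190) and MYL9 (-2.22 ± 0.173) were among them (list adjusted p = 9.96e-32). Of 27 TGF-beta and SMAD2/3 targets 6 had a lower effect, or 11 adjusted over the list alone (list adjusted p = 5.95e-14). CTGF differed between doses by -2.64 ± 0.202 and LEFTY2 by -6.22 ± 0.517. Of 18 pluripotency genes 7 had a higher effect, or 8 adjusted over the list alone, with ESRG at 3.81 ± 0.370 (list adjusted p = 4.36e-10), and of 8 genes of anterior identity 4 had (list adjusted p = 0.00035). OTX2, at 18.5 ± 2.83 CPM in low Wnt and 0.394 ± 0.265 CPM in high Wnt without SB4, differed between doses by 4.99 ± 0.877. These 4 lists kept their call with an estimated correlation. In high Wnt with and without SB4, 5 of the pluripotency and 2 of the anterior genes had 3 counts or fewer. LHX5 and DMBX1, also anterior, had 1 count each without SB4. All were too low to show a fall. Another 10 lists passed at the preset correlation only. Of 19 extracellular matrix genes 9 had a lower and 1 a higher effect, or 11 and 2 adjusted over the list alone (list adjusted p = 5.6e-08, adjusted p = 0.0534 with an estimated correlation). Of 11 neural plate border genes 4 had a higher and 1 a lower effect (list adjusted p = 5.61e-05, adjusted p = 0.164 with an estimated correlation), and of 20 cell cycle genes 3 had a higher one (list adjusted p = 0.00112, adjusted p = 0.172 with an estimated correlation). The others were ectomesenchyme and pharyngeal arch genes, mesenchymal genes, BMP targets, HOX genes of groups 1 to 5, central nervous system genes, genes of sensory and autonomic neurons, and FGF and ERK response genes, with list adjusted p from 0.00288 to 0.0424 and adjusted p from 0.126 to 0.357 with an estimated correlation. In all, 981 genes differed in their response to SB4, 438 with a higher and 543 with a lower effect in high Wnt, and 576 of them by at least 1 on the log2 scale (285 and 291). With library totals as the only scaling, 511 had a higher and 455 a lower effect.

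**Figure D4:**
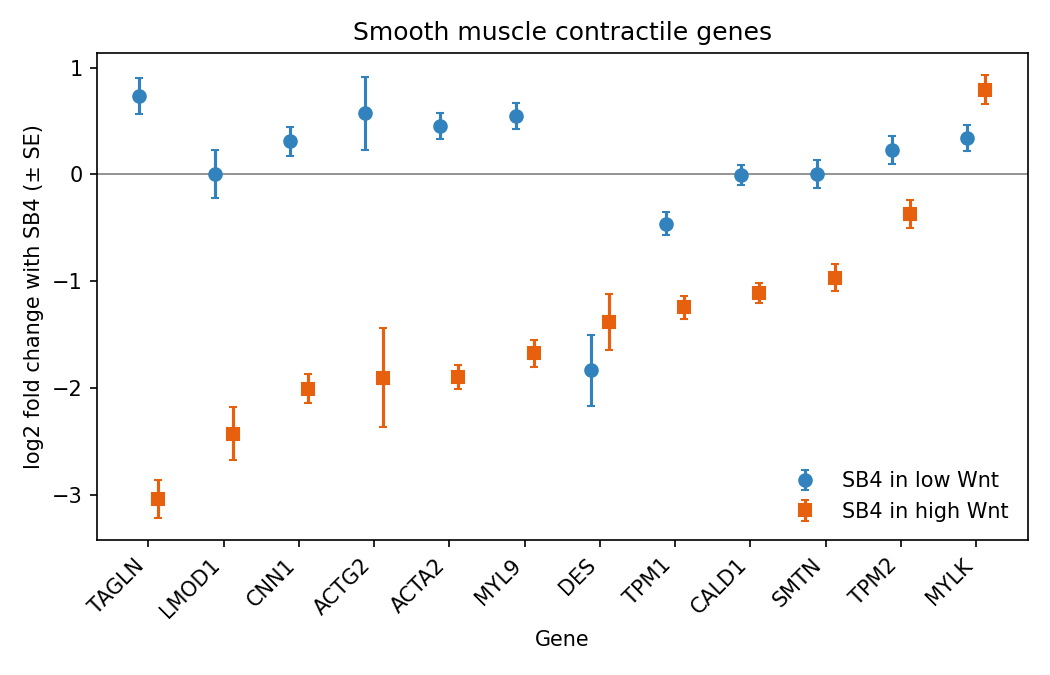
Effect of SB4 on 12 smooth muscle contractile genes in low Wnt and in high Wnt, as log2 fold change with its SE (2 libraries per group). TAGLN stands at 0.74 in low Wnt and -3.04 in high Wnt.

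For TGFB the largest differences between doses included VCAM1, which stood at 12.6 ± 0.348 CPM in low Wnt and 0.872 ± 0.0742 CPM with TGFB, against 5.40 ± 0.237 and 14.5 ± 0.958 CPM in high Wnt (SD, n = 2; difference 5.27 ± 0.251 SE). NR2F1 stood at 104 ± 4.72 and 34.8 ± 1.46 CPM in low Wnt and at 1.03 ± 0.191 and 12.6 ± 0.730 CPM in high Wnt (difference 5.20 ± 0.257). IGF2 stood at 10.9 ± 0.995 and 0.506 ± 0.112 CPM and at 11.7 ± 1.45 and 29.6 ± 5.01 CPM (difference 5.73 ± 0.411). CNTNAP4, a neuronal adhesion gene, stood at 0.543 ± 0.0783 and 9.17 ± 1.20 CPM and at 23.7 ± 2.11 and 6.99 ± 0.253 CPM (difference -5.82 ± 0.320). Of 12 epithelial genes 10 had a lower effect in high Wnt (list adjusted p = 6.04e-19). EPCAM differed between doses by -3.92 ± 0.292. Of 14 FGF and ERK response genes 7 did, or 9 adjusted over the list alone (list adjusted p = 4.61e-17). SPRY4 differed between doses by -3.75 ± 0.299. Of 18 pluripotency genes 10 did, or 11 adjusted over the list alone (list adjusted p = 4.64e-14). L1TD1 differed between doses by -3.46 ± 0.265. Of 15 axial progenitor genes 4 had a lower and 1 a higher effect, or 6 and 1 adjusted over the list alone (list adjusted p = 0.00152). These 4 lists kept their call with an estimated correlation, and another 10 passed at the preset correlation only. Of 12 retinoic acid response genes 5 had a higher and 2 a lower effect (list adjusted p = 7.21e-06, adjusted p = 0.0533 with an estimated correlation). MEIS2 differed between doses by 2.54 ± 0.168. Of 11 neural plate border genes 8 had a lower and 1 a higher effect (list adjusted p = 1.14e-05, adjusted p = 0.142 with an estimated correlation). Of 12 endoderm genes 3 had a lower effect, or 9 adjusted over the list alone, and 5 had 3 counts or fewer in high Wnt with and without TGFB (list adjusted p = 0.00122, adjusted p = 0.237 with an estimated correlation). Of 14 BMP targets 5 had a lower effect (list adjusted p = 0.00314, adjusted p = 0.267 with an estimated correlation), and of 17 stress and p53 response genes 6 had a lower and 1 a higher one (list adjusted p = 0.00541, adjusted p = 0.0713 with an estimated correlation). The others were genes of Schwann cells and glia, neural crest specifiers, Notch targets, Wnt targets, whose median of 0.04 differed in sign from their mean of -0.51 and their test, and central nervous system genes, with list adjusted p from 0.0105 to 0.0395 and adjusted p from 0.0716 to 0.323 with an estimated correlation. In all, 1905 genes differed in their response to TGFB, 926 with a higher and 979 with a lower effect in high Wnt, and 1064 of them by at least 1 on the log2 scale (430 and 634). The count was 1251 without low Wnt + TGFB replicate 2.

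The effects of the additives at the 2 doses were also compared across all 16149 tested genes, in pairs of contrasts with no library in common. These values are across genes, which are not independent replicates, so no p is given, and 8 such relations were computed. The effects of SB4 in low and in high Wnt had a Pearson r of 0.226 and a Spearman rho of 0.355, and of the 873 genes that passed in both, where 390.5 would be expected by chance, 764 changed in the same direction (87.5%). The effects of TGFB in low and in high Wnt had r = 0.13 and rho = 0.158, and 384 of 580 genes (66.2%; 304 expected) changed in the same direction, while r was 0.0544 without high Wnt + TGFB replicate 2. For SB4 in low Wnt with TGFB in high Wnt, r (-0.0175) and rho (0.0798) differed in sign, and r was 0.0247 without high Wnt + TGFB replicate 1 and 0.0101 without low Wnt replicate 2, so no direction is given. Both contrasts called 336 genes (131.4 expected), and 183 of them (54.5%) changed in the same direction. SB4 in high Wnt with TGFB in low Wnt had r = -0.0929 and rho = -0.00181, and r was -0.0439 without high Wnt replicate 1 and -0.0451 without high Wnt replicate 2. Of the 1273 genes that passed in both (903.2 expected), 579 (45.5%) changed in the same direction. Over 15845 genes simulated with no effect, r was 0.0186 for SB4 at both doses and 0.00988 for SB4 in low Wnt with TGFB in high Wnt. The effect of Wnt dose among cultures with SB4 had r = 0.276 (rho = 0.211) with that of TGFB in low Wnt. With that of TGFB in high Wnt it had r = -0.0232 (rho = -0.0374), which was 0.00232 without high Wnt + TGFB replicate 1 and 0.00514 without high Wnt + TGFB replicate 2. The effect of Wnt dose among cultures with TGFB had r = 0.27 (rho = 0.116) with that of SB4 in low Wnt and r = -0.177 (rho = -0.232) with that of SB4 in high Wnt, the latter -0.112 without high Wnt + SB4 replicate 2.

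Of 18 neural crest specifiers tested, 7 stayed under 10 CPM in every induced group. SOX10 had its highest group mean, 6.34 ± 0.220 CPM (SD, n = 2), in low Wnt + TGFB and stood at 5.64 ± 1.27 CPM in hESC. FOXD3 was highest in hESC, at 36.5 ± 6.37 CPM, and stood at 8.55 ± 1.33 CPM in low Wnt + TGFB and at 0.578 ± 0.311 CPM or less in the other induced groups. TFAP2A stood at 3.50 ± 0.472 CPM in low Wnt and 15.5 ± 5.09 CPM in low Wnt + TGFB, where it rose by 2.15 ± 0.329, and at 0.139 ± 0.197 CPM or less in the groups with the higher dose. NGFR, the low-affinity neurotrophin receptor, stood at 96.0 ± 4.04 CPM in low Wnt and 18.7 ± 0.748 CPM in high Wnt, and ETS1, a factor of cranial crest and endothelium, at 14.8 ± 1.47 and 56.0 ± 1.41 CPM. SNAI2 stood between 17.8 ± 2.94 and 66.6 ± 8.11 CPM in the 6 induced groups, against 0.868 ± 0.0282 CPM in hESC. As a list the specifiers did not pass for either additive at either dose, with adjusted p = 0.478 for SB4 and 0.0937 for TGFB in low Wnt, and 0.332 and 0.137 in high Wnt. Their TGFB effect differed between doses, with 4 of 18 lower in high Wnt and none higher (list adjusted p = 0.0116, adjusted p = 0.0716 with an estimated correlation; median -0.02, mean -0.44). Their median and mean differed in sign for TGFB in low Wnt (-0.09 and 0.45, test up), SB4 in high Wnt (0.03 and -0.01, test down) and TGFB in high Wnt (-0.27 and 0.01, test down).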

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

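Of the tests below, those of genes above their hESC level, of the share over list members, of low levels in low Wnt and of the mesoderm list were chosen only after the result was seen. What sets the following results apart is a tested difference between the effects of an additive in high Wnt and in low Wnt, given as a difference of log2 fold changes.

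The effect of SB4 differed between doses for 981 genes. The 5 highest differences were in TDGF1 (6.22), OTX2 (4.99), MARCH4 (3.99), SP5 (3.91) and NPTX1 (3.86), and the 5 lowest in LEFTY2 (-6.22), UNCX (-6.11), VCAM1 (-5.15), ACTC1 (-4.90) and JPH2 (-4.37). TDGF1 stood at 0.269 ± 0.0892 CPM in high Wnt and 0.493 ± 0.248 CPM with SB4 (SD, n = 2), so its difference came from a fall in low Wnt. SP5 had 3 counts in low Wnt + SB4. Its call (adjusted p = 0.00637) was lost without low Wnt + SB4 replicate 1 or 2. UNCX had no counts in low Wnt, so its fitted difference depends on the prior count. Its call (adjusted p = 0.0101) was lost without low Wnt replicate 1 or 2 or low Wnt + SB4 replicate 2. Of 14 lists with a different effect at the preset correlation, 4 kept their call with an estimated one. These and their medians were anterior identity (3.96), pluripotency (1.27), TGF-beta and SMAD2/3 targets (-0.74) and contractile genes (-1.66). Genes near 0 counts in high Wnt cannot fall there. Over genes with a fold at both doses, at their bounds where a group had no counts, the first 3 were 3.96 (6 of 8 genes), 0.71 (13 of 18) and -0.70 (26 of 27).

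The effect of TGFB differed between doses for 1905 genes. The 5 highest differences were in DBX1 (7.76), IGF2 (5.73), VCAM1 (5.27), NR2F1 (5.20) and NDE1 (4.58), and the 5 lowest in CNTNAP4 (-5.82), S100A14 (-5.35), SP5 (-5.13), VIL1 (-5.10) and POU5F1B (-4.96). DBX1 had no counts in high Wnt, so its fitted difference depends on the prior count. Its call was lost without high Wnt + TGFB replicate 1. NDE1, also listed on an alternate contig (adjusted p = 0.0473), lost its call with library totals only (0.0556), with DESeq2 (0.0544), with only the groups compared (0.0534) and without the hESC libraries (0.0608). Leaving out either library of high Wnt or of low Wnt + TGFB also ended it. So did leaving out high Wnt + TGFB replicate 1 or low Wnt replicate 2. VIL1 (adjusted p = 0.0401), with 3 counts in high Wnt and 2 with TGFB, lost its call with only the groups compared (0.0598). Leaving out either library of high Wnt or of high Wnt + TGFB, or low Wnt replicate 1, also ended it. POU5F1B, a retrocopy of POU5F1 that may share its reads, had 2 counts in high Wnt + TGFB and lost its call without high Wnt replicate 1 (0.059). Here too 4 of 14 lists kept their call with an estimated correlation. Those and their medians were epithelial genes (-2.82), pluripotency (-1.49), FGF and ERK response (-1.09) and axial progenitors (-0.86). Pluripotency had -1.44 over 13 genes counted in this way.

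Pluripotency and epithelial genes were higher with TGFB in low Wnt, and left-over stem cells were tested as an explanation. Library totals moved the median of all genes by only 0.082, and that of pluripotency stayed at 1.61. Only the choice of TMM is argued against. One share of unchanged stem cells could account for part of these lists. Over 80 genes specific to hESC the log2 ratio to hESC had an interquartile range of 0.985, just under its limit of 1.02. Their median level was 19.5% of hESC, against 1.68% in low Wnt. Over 22 members, not all of both lists, the log2 share had a range of 0.588 (0.349 between the 2 libraries). Shares ran from 4.75% to 66%, so 1 share does not give them all. The same share cannot give the 209 of 1199 genes raised at least 2-fold that also lay at least 2-fold above hESC (17.4%, under the bound of 20% set for excluding it), among them OTX2 at 2.25 ± 0.165 and FOXA2 at 6.85 ± 0.600 against hESC. Left-over or re-emerging stem cells and a response of the induced cells to TGFB both stay open.

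Contractile genes fell with SB4 in high Wnt and not, as a list, in low Wnt (median 0.27). Here too only TMM is argued against (median difference between doses -1.61 with library totals, median shift of all genes 0.0499). Low levels in low Wnt are argued against for 7 of the 10 genes that fell (70%), at 10 CPM or more there. Low levels stay open for the others (lowest 1.15 CPM), as 75% was set for excluding this. A smaller share of mesoderm-like cells could also account for it, as the mesoderm list had a median of -1.28 against -1.53 for contractile genes (interquartile ranges 1.20 and 0.855), although MEOX2 rose by 2.96 ± 0.495. A direct dependence of these genes on receptor activity at the higher dose remains a hypothesis beside it.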

How the results depend on the processing

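Results for the counts without genes higher in hESC, for the fit without hESC libraries and for correlations with 1 library left out are from alternatives chosen after the data were seen, and the other tests were planned. No named gene or list past the threshold changed direction under the settings below, but the larger side of the calls did in some contrasts and 2 of 8 correlations changed sign. The numbers of called genes stayed within 1.5 times with DESeq2, RLE, library totals, no filter, only the groups compared and no hESC libraries. Requiring a log2 fold change of at least 1 lowered them, by construction, to 6550, 6973, 2774, 711, 1654, 962, 428, 576 and 1064, in the order low Wnt and high Wnt against hESC, high against low Wnt, SB4 and TGFB in low Wnt, SB4 and TGFB in high Wnt, and the SB4 and TGFB differences between doses. Leaving out 1 library, where the lone one left is assumed to vary like the other groups, gave 10461 to 11111, 10766 to 11248, 4573 to 5108, 784 to 1067, 2347 to 3564, 1942 to 2424, 538 to 714, 661 to 775 and 1251 to 1731, lower since fewer samples are tested. Without genes higher in hESC than in high Wnt, SB4 and TGFB in low Wnt had 922 and 2239, fewer since fewer genes are counted.

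With library totals the larger side of the calls changed for high against low Wnt (3024 higher, 3145 lower), SB4 in high Wnt (2040, 1538) and the SB4 difference (511, 455). With DESeq2 it did for low Wnt (5214, 5680) and high Wnt against hESC (5435, 5752) and TGFB in high Wnt (574, 658), and with RLE for low Wnt (5547, 6005) and high Wnt against hESC (5670, 6003). With no filter it did for high against low Wnt (3124, 3321), with only the groups compared for high Wnt against hESC (5315, 5457), and without hESC libraries for TGFB in high Wnt (730, 791). At a log2 fold change of at least 1 it did for high Wnt against hESC (3484, 3489) and high against low Wnt (1353, 1421), and without genes higher in hESC for TGFB in low Wnt (551, 1688). Low Wnt against hESC had 5267 and 5288 without low Wnt replicate 1, 5300 and 5337 without low Wnt replicate 2 and 5229 and 5232 without hESC replicate 2, and high against low Wnt 2385 and 2446 without low Wnt replicate 1 and 2378 and 2444 without low Wnt replicate 2. The cause was not tested.

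Of 252 list tests 114 passed at the preset correlation and 44 with an estimated one (the cause was not tested), while 113 passed with RLE, 115 with library totals, 104 with no filter and 120 with the block. Of 699 pairs of named gene and contrast 587 passed, 83 of these lost a call without some library, and none changed sign. DESeq2 ended 10 calls and added 8. Among genes past the threshold in either contrast, r was 0.293 for SB4 at both doses, -0.043 for SB4 in low with TGFB in high Wnt, 0.313 for Wnt dose with TGFB and SB4 in low Wnt, 0.312 for Wnt dose with SB4 and TGFB in low Wnt, and -0.0398 for Wnt dose with SB4 and TGFB in high Wnt; the cause was not tested. With 1 library left out, r ran from 0.151 to 0.232 for SB4 at both doses, 0.0544 to 0.15 for TGFB at both doses, -0.0568 to 0.0247 for SB4 in low with TGFB in high Wnt, and -0.114 to -0.0439 for SB4 in high with TGFB in low Wnt. For Wnt dose with TGFB it ran from 0.218 to 0.266 (SB4 in low Wnt) and -0.197 to -0.112 (SB4 in high Wnt), and for Wnt dose with SB4 from 0.228 to 0.287 (TGFB in low Wnt) and -0.0409 to 0.00514 (TGFB in high Wnt). Library totals shifted the median of all genes by at most 0.0891.

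Replicate numbers recur in all groups, but the deviations of same-numbered libraries had r from -0.116 to 0.206, over 0.1 in 5 of 21 pairs of groups, and the labels tie no number to a shared batch, so the numbers were not taken as a pairing. All 3 pairs among the high Wnt groups were over 0.1 (high Wnt with SB4 0.206, high Wnt with TGFB 0.119, SB4 with TGFB 0.111), so a shared batch within that dose is not excluded. With the replicate block the counts were 11699, 11845, 6563, 2101, 4561, 3879, 1418, 1147 and 2129, no named gene lost its call and 8 gained one. Of the lists 8 gained a call and 2 lost it, retinoic acid response for TGFB in low Wnt (adjusted p = 0.0766) and FGF and ERK response for the SB4 difference between doses (0.0609). Depth limits genes near the floor, where few counts leave wide intervals, and for the SB4 difference between doses only 50.7% of simulated 2-fold changes were recovered.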

Other observations

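The test of a small share of crest cells was chosen only after the result was seen; the test of reads lost in counting was planned.

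Markers of melanocytes and of endothelium and blood did not move as lists in any contrast. For 7 melanocyte genes the adjusted p ran from 0.0538 (TGFB in high Wnt) to 0.824 (high Wnt against hESC), and for 9 endothelial and blood genes from 0.133 (SB4 in low Wnt) to 0.964 (SB4 in high Wnt). Single members did change. EDNRB, the endothelin receptor of crest and melanoblasts, fell by 4.78 ± 0.244 (SE) from hESC to low Wnt and was higher by 2.42 ± 0.249 in high Wnt than in low Wnt. MITF, the regulator of the melanocyte lineage, fell by 3.04 ± 0.396 in low Wnt against hESC, and the pigment cell gene PMEL rose by 0.85 ± 0.0984. TEK, the angiopoietin receptor gene, stood lower in high Wnt than in low Wnt, at -3.19 ± 0.119.

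Neural crest specifiers at a few CPM or less in induced cells were a pattern weighed after it was noticed. Of 18 tested, 7 stayed under 10 CPM in every induced group, with SOX10 at most at 6.34 CPM and TFAP2B at most at 4.38 CPM. Reads lost in counting are argued against, since 0% of those 7 were listed on several contigs or shared exon positions on their strand. A small share of crest cells among other cells could account for the low levels, in which case these genes would move together between doses: of the 6 at 1 CPM or more in low or high Wnt, 4 were lower in high Wnt (66.7%) and 0 were higher. That test was first written for all specifiers at 1 CPM or more, where 6 of 17 were higher and 7 lower, which speaks against a common share, and it was narrowed to the low ones after that result was seen, so it is weak evidence, and harvest at a stage before or after their peak was not tested.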
